A study of Arabidopsis thaliana with 128 samples.

How the data were processed

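Whole seedlings of 4 genotypes were grown for 5 d under constant light at 22 °C, treated with 1 mM cordycepin and sampled at 8 times, per the labels' protocols. Total RNA was depleted of ribosomal RNA with a plant RiboZero kit and made into TruSeq stranded libraries, per the labels' protocols. Quality checks, alignment and counting used FastQC, Bowtie2 2.2.3, TopHat2 2.0.12, SAMtools, HTSeq 0.6.1 and R 3.1.0 with the TAIR10 build, per the submitters' processing notes; the notes do not state the annotation, the filters or the strand setting of the counting. Antisense and overlapping genes are therefore uncertain, and so are near-identical copies such as VCS and VCR, the tubulin, LHCB2, Rubisco, FRO4 and FRO5, and histone genes. The labels note for 2 libraries, replicate 3 at 60 min of vcs and of vcs sov, that tubes had been swapped and the labels corrected.

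The authors deposited RPM values, in which the reads of each gene are scaled to a common library total, for 28775 genes in 128 libraries, with plastid (133) and mitochondrial (146) genes included in the total. Read counts were recovered from the deposited RPM, since every value in each library was a whole multiple of 1 read to within 0.001 reads. The recovered totals ranged from 11.5 to 37.4 M reads in genes per library. Plastid reads made up 21.5% to 60.7% of them and mitochondrial reads 1.31% to 3.40%. A second table holds, per the file headers, group means of scaled and normalized data, which are a ratio to 1 at 0 min of the same genotype. It also holds log2 fold changes and adjusted p-values of the authors' DESeq2 results, per the file headers; the samples and normalization behind them are not stated. The deposited table of library sizes was not used, because its sample names differ only by letter case and clash with names of other samples. The most similar pair of libraries, 7.5 and 15 min of vcs sov replicate 1, had a correlation of 0.997.

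Gene symbols came from a reference table for the TAIR10.1 assembly, used for names only because its build differs from that of the files. It matched 28009 gene identifiers, of which 10588 had a symbol. No coordinates are given for that reason.

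Abundance at 0 min was compared with limma 3.58.1 (trend and robust options) in R 4.3.3 on log2 of RPM plus a pseudocount of 0.5, over 16 libraries and the 19556 genes with a mean of at least 1 RPM in at least 1 genotype. Changes were also computed on RPM of nuclear genes alone (19343 genes, called nuclear RPM). For decline, the slope of log2 RPM on time was fitted to each of 16 time courses over 0 to 120 min (6 times, 96 libraries), for 15463 genes with at least 2 RPM at 0 min in every genotype. Each library was first scaled to 50 reference genes, the genes of at least 10 RPM with the highest unscaled slopes. Slopes were then compared with limma, n = 4 courses per genotype. Half-life in min is 60 divided by the negative slope in log2 units per h. All genotypes entered each fit, and tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Comparisons were sov against WT, vcs against WT, vcs sov against sov, vcs sov against vcs, and the interaction. Shares of reads and median slopes were compared with exact permutation tests. p-values treat the numbered biological replicates of the labels as independent samples.

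The reference genes have limits. Their unscaled slopes were 0.11 to 0.52 log2 units per h in WT, 0.13 to 0.56 in sov and 0.07 to 0.56 in vcs. In vcs sov they ran more widely, from -0.09 to 0.99, so single reference genes did not behave alike in all genotypes. Their median was 0.23 in WT, 0.22 in sov, 0.2 in vcs and 0.23 in vcs sov. The reference genes include HSP70, GSTF7, GSTF6 and other stress genes whose transcripts may have risen during treatment, and 2 of them are rRNA genes. Others are a non-coding RNA gene, AT1G15405, and RBCS1A, a Rubisco small subunit gene at 9758 RPM in WT at 0 min. Genes of the latter kind are also tested as a list below. Absolute half-lives therefore rest on the choice of reference genes, and a difference in reference transcripts between genotypes would shift all slopes of a genotype alike.

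The genes to name were chosen by a rule fixed before the data were examined, as were the comparisons, the filters and 24 gene lists. The rule took genes with a symbol past the threshold. For abundance and slopes it took the 10 largest changes in each direction (5 for vcs sov against vcs and the interaction) among genes of at least 5 RPM that moved the same way in all 4 same-numbered pairs. For decline in WT it took the 12 steepest and the 12 slowest genes. VCS, SOV and up to 4 examples per list were added. VCR, DCP2 and the genes without a symbol named for sov against WT fall outside the rule and were named after their values were seen, as were members of 3 gene lists added then (iron uptake, ABA receptors and clade A protein phosphatases 2C). The 24 lists cover anthocyanin synthesis, AUX/IAA, SAUR, JAZ, type-A response regulator, cell cycle, histone, circadian clock, heat shock protein, early stress and touch, pathogen response, ribosomal protein, nuclear photosystem and Rubisco small subunit, plastid-encoded, mitochondrion-encoded, mRNA decay factor, nuclear exoribonuclease and silencing, and commonly used reference genes, and markers of xylem, phloem, root hair, root tip, shoot meristem and stomatal lineage. Of their items 34 matched no gene, and the item TDT, meant for the decapping gene DCP2, matched a transporter of that name. Lists of at least 5 tested genes were tested with camera (preset correlation 0.01), and again with the correlation estimated from the data.

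Alternatives were another pseudocount (0.1 or 2), no filter on low values, a minimum of 5 RPM for abundance or 10 RPM for slopes, centring on the nuclear median, edgeR 4.0.16 (quasi-likelihood test with TMM factors on the recovered counts), the replicate number as a block, and each replicate left out, alone or in all genotypes. For slopes they also were no stable scaling, 200 reference genes, windows of 0 to 60 and 0 to 480 min, a fit of genotype by time over 96 libraries, and leaving out the libraries of the swapped tubes. Chosen after the data were seen were 5 more for slopes: nuclear RPM with no stable scaling, each course centred on its median slope, the next 50 reference genes, a window of 7.5 to 120 min and reference genes without the rRNA genes.

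The tests were tried on counts simulated from the WT means at 0 min and, for slopes, the WT slopes. They used the real library sizes and the same preset dispersion, the spread of counts between replicates, for all genes. Changes were put into the vcs libraries alone, and slope changes were all towards slower decline. For abundance of vcs against WT over 18029 genes, 56.7%, 100% and 100% of genes changed 1.5-fold, 2-fold and 4-fold (67, 67 and 66 genes) were recovered, with 12 false calls. For slopes of vcs against WT over 15563 genes, 13.4%, 94.0% and 100% of genes changed by 0.25, 0.5 and 1 log2 unit per h were recovered, with 8 false calls. The changed genes there were picked for a steep WT decline. An earlier simulation in which changed transcripts were allowed to rise failed. In it 35 changed genes entered the reference set and 15192 of 15544 genes were called falsely, which shows how far the method depends on reference genes that behave alike in all genotypes. Other tools were the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.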

Results

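Total RNA was sequenced from whole 5-d-old Arabidopsis thaliana seedlings of 4 genotypes during a block of transcription. Seedlings were vacuum infiltrated with cordycepin, an adenosine analogue that stops transcription, and sampled at 8 times: at 0 min, every 7.5 min up to 15 min, and then at 30, 60, 120, 240 and finally 480 min. VARICOSE (VCS, AT3G13300) is a scaffold of the cytoplasmic mRNA decapping complex. SUPPRESSOR OF VARICOSE (SOV, AT1G77680) is a DIS3L2-type exoribonuclease that degrades RNA from the 3' end. Per the labels, WT is accession Col-0 with a SOV transgene from Landsberg erecta, and sov is Col-0 itself. The genotype vcs carries the vcs-7 mutation with the same transgene, and vcs sov carries vcs-7 without it. Each of the 32 groups had 4 libraries, numbered as biological replicates in the labels. The libraries held 11.5 to 37.4 M reads in genes, with a median of 21.7 M. A level of 3 reads corresponds to 0.0803 to 0.261 RPM, the reads of a gene scaled to a common library total, depending on the library. Intervals and floors of this kind cover counting error only.

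The targeted genes were examined first. At 0 min, VCS stood at 66.2 ± 9.29 RPM in WT and 66.7 ± 3.62 in sov, against 4.49 ± 0.34 in vcs and 9.13 ± 0.56 in vcs sov (SD, n = 4). SOV stood at 98.5 ± 13.95 RPM in WT and 21.0 ± 4.95 in sov (SD, n = 4). In the vcs backgrounds SOV was more abundant, at 516.5 ± 41.2 RPM in vcs and 182.1 ± 14.9 in vcs sov (SD, n = 4), so that without the transgene it still stood above WT there. VCR (AT3G13290), the neighbouring copy related to VCS, rose from 24.8 ± 2.72 RPM in WT to 46.0 ± 0.841 in vcs, and from 26.1 ± 0.671 in sov to 64.9 ± 4.45 in vcs sov (SD, n = 4). Reads that VCS and VCR share could move between the 2 genes, so the remaining VCS signal in vcs is uncertain. Relative to the reads of nuclear genes, SOV rose by 2.03 (SE 0.15) on the log2 scale from WT to vcs, and by 2.61 (SE 0.15) from sov to vcs sov. VCS differed by -4.15 and -3.34 in the same comparisons.

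The share of reads from nuclear genes differed between genotypes. At 0 min it was 49.1% ± 1.8 in WT, 51.25% ± 0.93 in sov, 63.2% ± 1.32 in vcs and 73.5% ± 1.66 in vcs sov (SD, n = 4); nearly all other reads came from plastid genes. In a two-sided exact permutation test, vcs exceeded WT by 14.2 percentage points, vcs sov exceeded sov by 22.2 and vcs sov exceeded vcs by 10.2, each with p = 0.0286, the smallest p that 4 against 4 allow (adjusted p = 0.0381 over 4 comparisons). The sov libraries exceeded WT by 2.16 points (exact p = 0.0571, also the adjusted p). At 480 min the nuclear shares were 39.1%, 40.01%, 52.9% and 67.2% in WT, sov, vcs and vcs sov. Nuclear genes of the photosystems and the Rubisco small subunit took 11.2% ± 0.6 of nuclear reads in WT, 11.8% ± 1.6 in sov, 8.35% ± 0.65 in vcs and 4.86% ± 0.44 in vcs sov at 0 min (SD, n = 4). On RPM as deposited, which includes plastid reads, the median nuclear gene was 0.50 (log2) higher in vcs than in WT and 0.64 higher in vcs sov than in sov. With RPM recomputed on nuclear genes alone (nuclear RPM), those shifts were 0.17 and 0.17, and that from vcs to vcs sov was -0.02. Log2 changes of single genes below are in nuclear RPM and levels are in RPM as deposited.

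**Figure D1:**
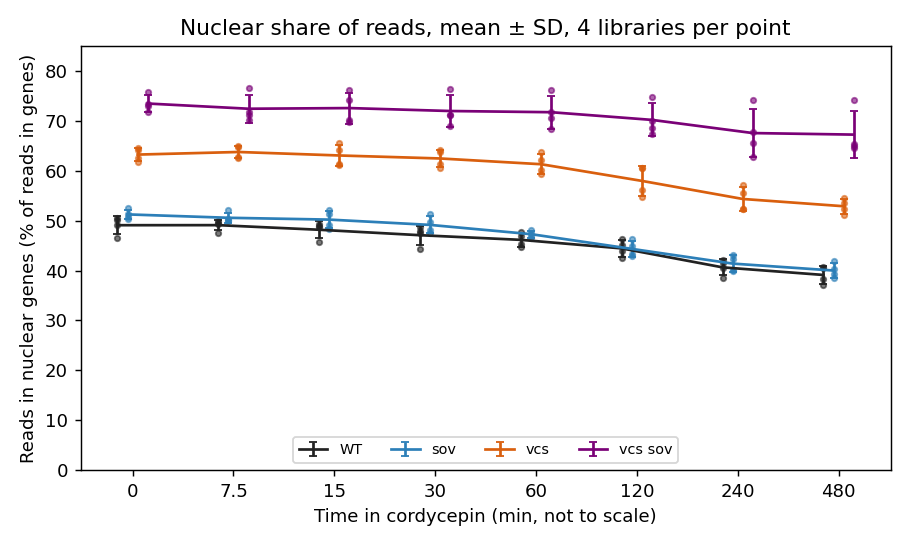
Share of reads from nuclear genes (percent of reads in genes, y axis) against minutes after cordycepin (x axis), as the mean and SD of 4 libraries per genotype and time. At 0 min the share was lowest in WT (49.1%) and highest in vcs sov (73.5%).

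The comparison of sov with WT asks what the lack of the SOV transgene does where VCS is intact. Few transcripts differed at 0 min. Apart from SOV itself, which was lower in sov by -2.30 (log2; limma adjusted p = 6.08e-08), 5 genes were lower and 2 were higher. AT5G24240 fell from 7.51 ± 1.44 RPM in WT to 0.433 ± 0.1 in sov, and AT5G26270 from 12.5 ± 0.888 to 3.96 ± 0.889 (SD, n = 4). TBL30, AT1G60110 and AT3G08640 were also lower, by -2.07, -1.85 and -0.57 (log2). AT1G31150 was higher in sov, at 8.32 ± 1.01 RPM against 3.099 ± 0.62 in WT, and so was AT4G04223, at 3.45 ± 1.71 against 1.09 ± 0.358 (SD, n = 4). In all, limma called 2 genes higher and 6 lower among 19556, with 916 genes at an unadjusted p under 0.05. edgeR called 1 higher and 6 lower. Without replicate 3 of every genotype the count was 5. The authors' deposited table holds 8 higher and 13 lower genes for this comparison. No member of the early stress and touch list (30 genes, median -0.28 log2) passed the test, although camera placed that list below the other genes (adjusted p = 3.51e-08, and adjusted p = 0.927 with an estimated correlation). Camera also called the heat shock protein list (median 0.12, adjusted p = 0.0123) and the type-A response regulators (median 0.23, adjusted p = 0.0336), with no member passing. Both had an adjusted p = 0.927 with an estimated correlation.

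The comparison of vcs with WT asks what loss of the decapping scaffold does where SOV is active. Transcripts of BAM5, a beta-amylase, rose from 0.13 RPM in WT to 11.04 in vcs, a change of 4.45 (SE 0.26) in log2 nuclear RPM. CORI3, a coronatine-induced gene, rose by 3.79 (SE 0.37), from 4.40 to 85.02 RPM. The alpha-tubulin genes TUA2 and TUA6 rose by 3.35 (SE 0.09) and 2.97 (SE 0.08), from 89.0 and 141.5 RPM in WT to 1172 and 1433 in vcs; near-identical tubulin copies could share these reads. The tonoplast aquaporin genes TIP2;3 and TIP2;2 rose by 3.53 (SE 0.20) and 2.99 (SE 0.14), and RAP2.4, which encodes an ERF-family transcription factor, rose by 3.22 (SE 0.11). In the other direction, genes of the chlorophyll a/b-binding proteins LHCB2.3 and LHCB2.2 fell by 3.62 (SE 0.34) and 3.30 (SE 0.28) on the log2 scale, with levels of 186.6 and 487.4 RPM in WT against 19.5 and 65.5 in vcs. CCA1, a MYB factor of the circadian clock, fell by 3.00 (SE 0.13), from 64.6 to 10.2 RPM, and FTM1 differed by -4.14 (SE 0.50). All these values are means of 4 libraries per genotype. In WT, BAM5 had only 13 reads over the 4 libraries, so its fitted change depends on the pseudocount.

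Among 19556 genes, limma called 13071 higher and 935 lower in vcs than in WT on RPM as deposited, so that 93.3% of calls were higher. On nuclear RPM the calls were 7022 higher and 2528 lower among 19343 genes, with 1392 and 360 of them changed by at least 1 log2 unit. After centring each library on its nuclear median, 3654 were higher and 5471 lower, and edgeR called 4666 higher and 4470 lower. The balance of higher and lower calls therefore depends on the scaling. The authors' deposited table holds 4530 higher and 4670 lower genes.

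Of the gene lists, cell cycle genes were mostly higher in vcs. On nuclear RPM, 32 of 41 were higher, 1 was lower and 8 did not pass, with a median change of 0.65 (log2); adjusted over the list alone, 34 were higher and 1 lower. CYC3B, CYCD1;1 and CYCB1;4, all cyclin genes, rose by 1.81, 1.59 and 1.58. This was the only list on nuclear RPM whose camera call (adjusted p = 1.29e-05) held with an estimated correlation (adjusted p = 0.0179 with an estimated correlation). Of 48 nuclear photosystem and Rubisco small subunit genes, 39 were lower, 1 was higher and 8 did not pass, as they did adjusted over the list alone (median -0.66; camera adjusted p = 4.31e-23, adjusted p = 0.115 with an estimated correlation). The nuclear photosystem genes thus moved with the plastid share of the libraries. Heat shock protein genes had 20 of 29 higher and none lower, Hsp70-2 by 2.58 and HSP17.6A by 1.52, but camera did not call the list (adjusted p = 0.0768). The AUX/IAA genes, which encode repressors of auxin response, had 14 of 23 higher and none lower (camera adjusted p = 0.231). SAUR genes, which respond early to auxin, had 20 of 45 higher and 3 lower (camera adjusted p = 0.0635). Clock genes went both ways, with 9 of 20 higher, such as PRR3 by 1.96, and 7 lower, such as LHY by -2.69 (camera adjusted p = 0.308). Here and below, a count adjusted over the list alone was identical where none is given. On RPM as deposited, 88 plastid-encoded genes were lower, none was higher and 40 did not pass (median -0.43; camera adjusted p = 1.24e-66, adjusted p = 0.00206 with an estimated correlation). Of 85 mitochondrion-encoded genes, 9 were higher, 5 lower and 71 did not pass, or 5 higher and 1 lower adjusted over the list alone; their median of 0.03 lay below that of all genes (camera adjusted p = 1.68e-10, adjusted p = 0.122 with an estimated correlation).

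The comparison of vcs sov with sov asks what the vcs-7 mutation does where the SOV transgene is missing too. Among the genes with the largest rises, LEA7, a late embryogenesis abundant protein gene, stood at 165.6 RPM in vcs sov against 0.0954 in sov, a change of 8.33 (SE 0.29) in log2 nuclear RPM; the 10 reads of LEA7 over the 4 sov libraries make that value depend on the pseudocount. RD20, which encodes a caleosin, rose by 6.37 (SE 0.36), from 0.702 to 113.4 RPM. The dehydrin gene RAB18 rose by 6.36 (SE 0.29), from 0.377 to 74.6 RPM, and COR15A, which encodes a cold-induced chloroplast protein, rose by 5.92 (SE 0.55), from 1.16 to 118.8 RPM. The lipid transfer protein gene LTP3 rose by 6.88 (SE 0.35) and the subtilase gene ATSBT5.2 by 5.85 (SE 0.13), the latter from 6.42 to 556.1 RPM. FRO2, the ferric chelate reductase, fell by 4.34 (SE 0.46), from 52.1 to 3.95 RPM, and IRT1, the main iron transporter of the root, fell by 3.95 (SE 0.38), from 52.5 to 5.06 RPM. CYP82C4, a cytochrome P450 gene, and MLP34, a major latex protein-like gene, differed by -4.24 (SE 0.46) and -4.42 (SE 0.26). All these values are means of 4 libraries per genotype.

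Among 19556 genes, limma called 12971 higher and 2504 lower in vcs sov than in sov on RPM as deposited (83.8% higher). On nuclear RPM, 8216 were higher and 5243 lower (61.0% higher), with 3141 and 1690 of them changed by at least 1 log2 unit. Centring on the nuclear median gave 6252 higher and 7480 lower, and edgeR gave 6862 and 6841. The authors' deposited table holds 6812 higher and 6438 lower genes.

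All 48 nuclear photosystem and Rubisco small subunit genes were lower in vcs sov than in sov on nuclear RPM, also adjusted over the list alone, with a median change of -1.16 (log2; camera adjusted p = 1.27e-17, adjusted p = 0.235 with an estimated correlation). RBCS2B, LHCB2.3 and RBCS1B differed by -2.73, -2.59 and -2.22. All 10 markers of xylem and secondary walls were higher, also adjusted over the list alone (median 1.42; camera adjusted p = 0.00287, adjusted p = 0.816 with an estimated correlation). They include VND7, a master regulator of vessel formation, by 2.31, the vessel protease gene XCP1 by 1.59 and the cellulose synthase gene IRX1 by 1.54. Of 9 stomatal lineage markers, 7 were lower and 2 did not pass, or 7 lower and 1 higher adjusted over the list alone (median -0.88; camera adjusted p = 0.0143, adjusted p = 0.765 with an estimated correlation). SPCH, which starts the lineage, differed by -1.82, and EPF2, a peptide that limits it, by -1.78. Cell cycle genes had 28 of 41 higher and 2 lower (camera adjusted p = 0.0135, adjusted p = 0.235 with an estimated correlation). Cytosolic ribosomal protein genes had 20 of 37 lower and 7 higher (median -0.32; camera adjusted p = 0.0135, adjusted p = 0.929 with an estimated correlation); their direction turned on RPM as deposited, where 13 were higher and 4 lower. Plastid-encoded genes on that scale had 115 lower, 13 not passing and none higher, or 116 lower adjusted over the list alone (camera adjusted p = 5.70e-52, adjusted p = 0.00620 with an estimated correlation). Of 85 mitochondrion-encoded genes on that scale, 41 were higher and 13 lower, or 40 and 13 adjusted over the list alone; their median of 0.35 again lay below that of all genes (camera adjusted p = 0.0347, adjusted p = 0.993 with an estimated correlation).

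The other lists had no camera call in vcs sov against sov on nuclear RPM, with adjusted p from 0.0797 for phloem markers (4 of 7 lower) to 0.942 for clock genes (8 of 20 higher, 4 lower). Heat shock protein genes had 18 of 29 higher and 7 lower, HSP17.6A by 4.61 and HSP18.2 by 3.64. Early stress and touch genes had 17 of 30 higher and 2 lower, or 16 and 2 adjusted over the list alone, with WRKY46 up by 3.47 and CML37 by 2.59. Pathogen response genes had 6 of 12 higher and 2 lower, with PBS3, which acts in salicylic acid synthesis, up by 4.35. Cytoplasmic mRNA decay factors had 14 of 28 higher and 7 lower, and nuclear exoribonuclease and silencing genes had 5 of 20 higher and 5 lower. SAUR genes had 23 of 45 higher and 8 lower, AUX/IAA genes 11 of 23 and 3 (9 and 3 adjusted over the list alone), and type-A response regulators 2 of 9 and 2. JAZ genes had 4 of 12 higher and 2 lower, histone genes 6 of 22 and 7, and anthocyanin synthesis genes 2 of 9 and 2. Root hair markers had 5 of 8 higher and 2 lower, and shoot meristem and organ boundary markers 4 of 6 and 2. All 3 root tip markers were higher, too few for a list test, and commonly used reference genes had 7 of 14 higher and 2 lower.

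The comparison of vcs sov with vcs asks what the lack of the SOV transgene does in the vcs-7 mutant. CER1, which acts in the synthesis of wax alkanes, stood at 157.4 RPM in vcs sov against 2.06 in vcs, a rise of 5.82 (SE 0.20) in log2 nuclear RPM, while WT and sov had 11.2 and 11.4 RPM. LEA7, RAB18 and RD20 rose by 6.23 (SE 0.29), 5.58 (SE 0.29) and 5.38 (SE 0.36), and ORP4C by 5.05 (SE 0.29). ACD6, a regulator of defence, fell by 4.99 (SE 0.37), from 71.4 RPM in vcs to 2.65 in vcs sov, and IRT1, FRO2, CYP82C4 and MLP328 differed by -4.10, -3.87, -4.39 and -3.62. LHCB2.2 and LHCB2.1 were higher in vcs sov by 2.51 and 2.00, although the list of nuclear photosystem genes had 27 of 48 lower and 6 higher, or 28 and 6 adjusted over the list alone (camera adjusted p = 0.00686, adjusted p = 0.954 with an estimated correlation). All 10 xylem markers were again higher (median 1.10; camera adjusted p = 0.000135, adjusted p = 0.693 with an estimated correlation) and all 9 stomatal lineage markers were lower, TMM by -1.46 (median -0.93; camera adjusted p = 0.00686, adjusted p = 0.693 with an estimated correlation). Both counts were identical adjusted over the list alone. In all, limma called 7985 genes higher and 3520 lower on RPM as deposited (69.4% higher), 5144 and 5580 on nuclear RPM (48.0% higher), and 5424 and 5847 after centring. edgeR called 5428 higher and 5764 lower, and the authors' deposited table holds 5656 higher and 5346 lower genes.

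The interaction tests whether the change from sov to vcs sov differs from that from WT to vcs. Among genes with a symbol and at least 5 RPM in 1 genotype, it was largest for LEA7 at 6.68 (SE 0.41), CER1 at 5.84 (SE 0.29), RD20 at 5.29 (SE 0.52), LTP3 at 5.13 (SE 0.50) and RAB18 at 4.96 (SE 0.41), in log2 nuclear RPM. It was most negative for ACD6 at -4.66 (SE 0.52), IRT1 at -4.43 (SE 0.53), CYP82C4 at -4.40 (SE 0.66), FRO2 at -4.27 (SE 0.65) and MLP34 at -3.65 (SE 0.37). On nuclear RPM, 3699 genes had a positive and 4068 a negative interaction among 19343, and 5294 and 2833 did on RPM as deposited. All 10 xylem markers were positive (camera adjusted p = 0.000298, adjusted p = 0.703 with an estimated correlation), and so were 10 of 30 early stress and touch genes, or 9 adjusted over the list alone (camera adjusted p = 0.00908, adjusted p = 0.922 with an estimated correlation). Stomatal lineage markers had 5 of 9 negative, or 6 adjusted over the list alone (camera adjusted p = 0.00838, adjusted p = 0.703 with an estimated correlation). Nuclear photosystem genes had 21 of 48 negative and 3 positive, or 23 and 5 adjusted over the list alone (camera adjusted p = 0.00441, adjusted p = 0.922 with an estimated correlation). Ribosomal protein genes had 11 of 37 negative and 2 positive (camera adjusted p = 0.0365, adjusted p = 0.922 with an estimated correlation). The SOV interaction was 0.58 (adjusted p = 0.0346); on RPM as deposited it was 0.72 (adjusted p = 0.00720) and lost its call without replicate 2 of every genotype (0.60, adjusted p = 0.0674).

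The effect of vcs in the background with the SOV transgene and in that without it comes from separate libraries. Across 19343 genes, the 2 sets of log2 changes in nuclear RPM had a Pearson r of 0.664; genes are not independent replicates. Of the genes higher in either comparison 5161 were shared, where independent lists would share 2982.6, and 1932 lower genes were shared against 685.2. Another 518 genes were called in opposite directions, CER1 (-2.65 and 3.20) and ACD6 (1.93 and -2.74) among them. The log2 changes in the authors' deposited table had a Pearson r with those in nuclear RPM of 0.984 for sov against WT, 0.995 for vcs against WT, 0.996 for vcs sov against sov and 0.995 for vcs sov against vcs, over 18470 genes. All 6946, 11863 and 9924 genes called in both sources for the last 3 comparisons had the same sign.

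Decline after cordycepin was measured as the slope of log2 RPM over 0 to 120 min, after scaling each library to 50 genes taken as stable. In WT, the median transcript halved in 131.7 min. Among genes with a symbol, the fastest declines were those of BT2 at -2.50 ± 0.16 and BT1 at -2.32 ± 0.23 log2 units per h (SD, n = 4), half-lives of 24.0 and 25.9 min; both encode BTB and TAZ domain proteins. COL2, a CONSTANS-like gene, followed at -2.33 ± 0.13 (SD, n = 4), then the transcription factor genes DDF1 and GLK2 at -2.08 each. At the other end, HSP70, the glutathione transferase gene GSTF7 and the alternative oxidase gene AOX1A rose against the reference genes, by 0.26, 0.20 and 0.13 log2 units per h. They are among the 50 reference genes themselves, so their slopes are not independent of the scaling. HSP70 lost its call without WT replicate 1, 2 or 4 (0.22, 0.23 and 0.24), and AOX1A without WT replicate 4 (0.07) and over 0 to 60 min (-0.04). GSTF7 was not called over 0 to 60 min (0.10). POM1 declined at -0.08, but its slope was 0.18 with no stable scaling. Of 15463 genes, limma called 14944 declining and 50 rising in WT. The reference genes were picked for the highest slopes, so most other genes had to decline against them. This count therefore does not measure how many transcripts decayed.

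All 6 type-A response regulators declined in WT with a median of -1.40 log2 units per h, all 11 JAZ genes, repressors of jasmonate signalling, with -1.36, all 20 histone genes with -1.06, all 30 early stress and touch genes with -0.88 and all 27 cell cycle genes with -0.81. The same numbers passed adjusted over the list alone. Camera placed these lists below the median gene, with adjusted p of 0.000405, 0.00253, 0.00562, 0.000342 and 0.000173; the values with an estimated correlation were adjusted p = 0.138, 0.500, 0.638, 0.604 and 0.299. Slower lists were the nuclear photosystem genes with a median of -0.22 (48 of 48 declining, camera adjusted p = 8.46e-05, adjusted p = 0.604 with an estimated correlation) and the ribosomal protein genes with -0.26 (35 of 36, camera adjusted p = 0.00147, adjusted p = 0.650 with an estimated correlation). All 14 commonly used reference genes declined, with a median of -0.21 (camera adjusted p = 0.0179, adjusted p = 0.604 with an estimated correlation). These last 3 medians lie above 0 when nuclear RPM is used with no reference genes, since the WT median is then -0.165 in place of -0.458. Heat shock protein genes had 9 of 19 declining and 3 rising, or 7 and 3 adjusted over the list alone (median -0.09; camera adjusted p = 3.18e-21, adjusted p = 0.166 with an estimated correlation). Mitochondrion-encoded genes had 40 of 60 declining, or 34 adjusted over the list alone (camera adjusted p = 1.01e-23, adjusted p = 0.172 with an estimated correlation).

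The median half-life was 131.7 min in WT, 118.7 in sov, 147.1 in vcs and 175.3 in vcs sov, over 15463 genes. Transcripts with a half-life under 60 min numbered 1009, 1324, 595 and 271. These half-lives depend on the scaling. With 200 stable genes the WT median was 152.9 min, with no stable scaling 265.2 min and on nuclear RPM alone 364.7 min, against 216.0, 728.2 and 1067 min in vcs sov. Half-lives from the group means in the authors' deposited table were 152.6, 132.8, 171.3 and 261.4 min for WT, sov, vcs and vcs sov. Two-sided exact permutation tests on the median slopes of the 4 time courses per genotype did not pass after adjustment. The median slope of vcs sov exceeded that of sov by 0.16 log2 units per h (exact p = 0.0571, adjusted p = 0.190), that of vcs exceeded that of WT by 0.05 (exact p = 0.143, adjusted p = 0.190) and that of vcs sov exceeded that of vcs by 0.06 (exact p = 0.200, also the adjusted p). The sov courses were lower than WT by -0.05 (exact p = 0.143, adjusted p = 0.190), and the smallest p possible was 0.0286. Without vcs sov replicate 4, the difference between vcs sov and sov was 0.20. Its exact p = 0.0286, not adjusted, is the smallest that 3 courses against 4 allow. Replicate 4 was the only vcs sov course to overlap those of sov (-0.4454 against -0.5427 to -0.4381). Leaving it out therefore fixed this p, which is no separate support. With all 4 courses, the 2 rRNA genes were also left out of the references. The difference between vcs sov and sov was then 0.19 (exact p = 0.0286, adjusted p = 0.0571). On those references vcs exceeded WT by 0.06, vcs sov exceeded vcs by 0.08 and sov differed from WT by -0.05. Each of these had an exact p = 0.0571, also the adjusted p.

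**Figure D2:**
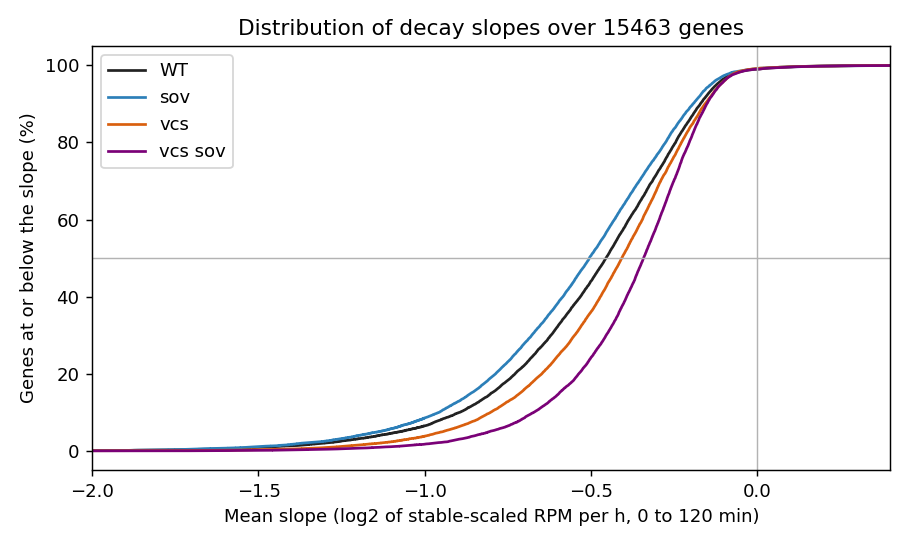
Cumulative share of the 15463 tested genes (y axis) against the slope of decline in log2 units per h (x axis), 1 line per genotype, from the mean of 4 time courses. The curve of sov lies farthest to the left (median half-life 118.7 min) and that of vcs sov farthest to the right (175.3 min).

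Between sov and WT, limma called 0 of 15463 slopes, with 1141 at an unadjusted p under 0.05. Every other setting run also gave 0 calls, among them no stable scaling (1686 at an unadjusted p under 0.05), each course centred on its median (975) and a window of 0 to 60 min (386). Time courses were simulated for vcs against WT with a preset dispersion. Slowings of 0.25, 0.5 and 1 log2 unit per h were recovered for 13.4%, 94.0% and 100% of genes, so small differences limited to few genes would mostly go undetected. Camera called 5 lists, though none of their members passed; for ribosomal protein genes the median difference was -0.11 (adjusted p = 8.34e-05, adjusted p = 0.871 with an estimated correlation). With an estimated correlation it called 0 lists.

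In vcs, some transcripts declined more slowly than in WT. JAZ8, a jasmonate repressor gene, changed by 1.19 (SE 0.21) log2 units per h, from a half-life of 31.8 min in WT to 85.8 min in vcs. CIL changed by 1.18 (SE 0.10), from 32.1 to 87.9 min, and TCP11 (AT5G08330), a transcription factor gene, by 1.07 (SE 0.09), from 31.9 to 73.9 min. COL2 and BT1 changed by 1.07 (SE 0.11) and 0.97 (SE 0.12), to half-lives of 47.8 and 44.5 min, and the histone H2B gene HTB2 by 0.96 (SE 0.12), from 34.2 to 75.6 min. Other transcripts declined faster in vcs. The B-box gene BBX15 differed by -1.18 (SE 0.13), from a half-life of 57.7 min to 27.0 min, and RAP2.4 by -0.92 (SE 0.09), from 106.8 to 40.5 min. By 30 min RAP2.4 had fallen alike, by -0.872 (log2) in WT and -0.734 in vcs. In WT it then slowed, to -1.12 at 60 min and -1.186 at 120 min, against -1.704 and -2.908 in vcs. The RAP2.4 difference thus arose after 30 min, and its WT half-life averages over both phases. The cytokinin response factor genes CRF6 and CRF5 differed by -1.09 (SE 0.07) and -0.72 (SE 0.12), and VCS itself by -0.58 (SE 0.08). In WT the CRF6 slope was 0.08, and -1.01 in vcs. By 60 min, CRF6 had fallen alike from its 0 min level, by -1.39 (log2) in WT and -1.43 in vcs. In WT it then returned to -0.03 at 120 min and 1.02 at 480 min, against -2.05 and -1.15 in vcs. Its difference thus arose after 60 min, when CRF6 rose in WT. Over 0 to 60 min, CRF5 differed by 0.25, CRF6 by -0.11 and BBX15 by -0.63, none of them called; over 0 to 480 min all 3 were called, at -0.25, -0.36 and -0.34. JAZ8 was not called with a pseudocount of 2 (0.55, adjusted p = 0.0784), and BT1 was not called over 0 to 480 min (0.06, adjusted p = 0.0627). SOV did not pass (-0.07, SE 0.09, adjusted p = 0.607).

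Of 15463 genes, limma called 2528 slower and 858 faster in vcs than in WT (74.7% slower). After centring each course on its median slope, 2114 were slower and 2050 faster (50.8% slower), and without the 2 rRNA genes among the reference genes 3362 were slower and 959 faster. The count of 3386 fell to 2003, 1840 and 2203 without replicate 2, 3 or 4 of every genotype.

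**Figure D3:**
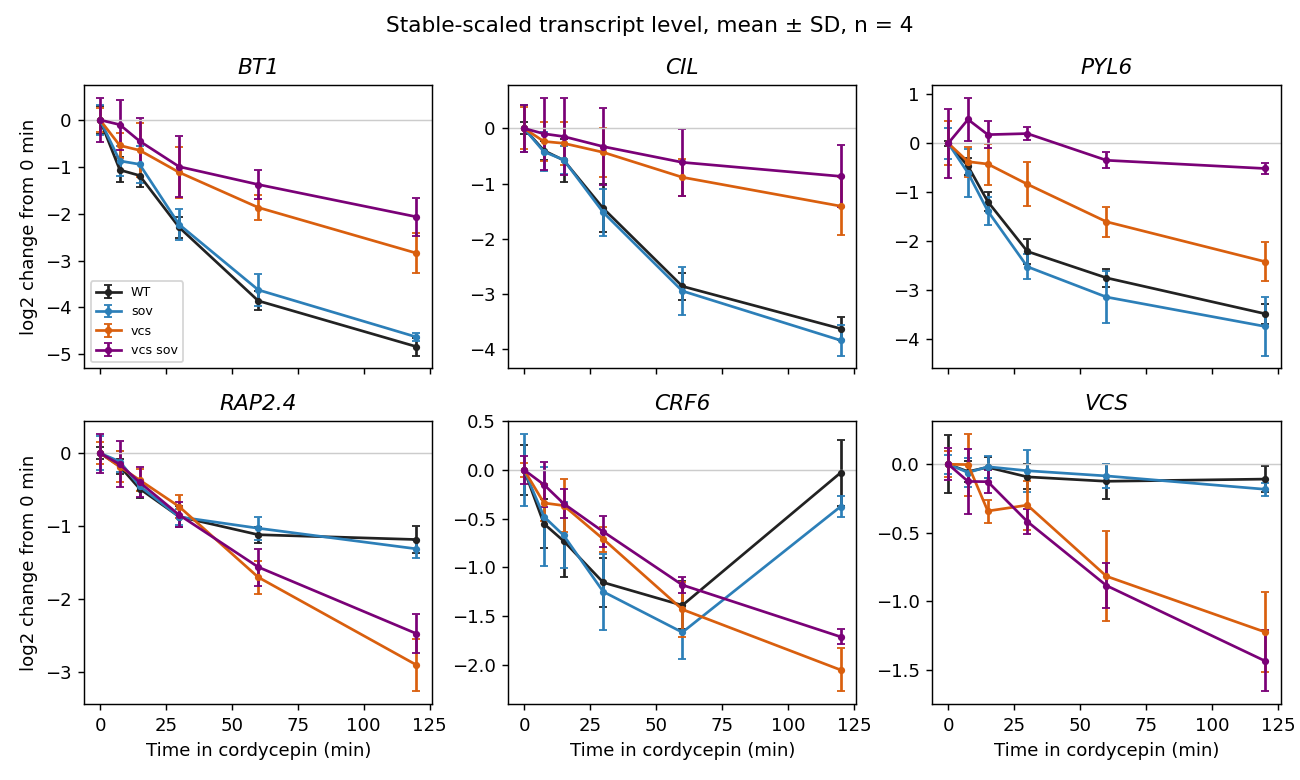
Log2 change from 0 min of the scaled RPM (y axis) over 0 to 120 min (x axis) for BT1, CIL, PYL6, RAP2.4, CRF6 and VCS, as mean and SD of 4 time courses per genotype. By 120 min BT1 and CIL had fallen furthest in WT and sov, and RAP2.4 in vcs and vcs sov. Up to 30 min RAP2.4 fell alike in all genotypes.

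Of the lists, JAZ genes had 10 of 11 slower in vcs and none faster, JAZ7 by 1.02 and JAZ6 by 0.96 (median 0.68; camera adjusted p = 1.42e-07, adjusted p = 0.294 with an estimated correlation). Histone genes, whose copies can share reads, had 14 of 20 slower and none faster, HTB9 by 0.86 and HTB11 by 0.82 (median 0.44; camera adjusted p = 7.21e-09, adjusted p = 0.345 with an estimated correlation). Both counts were identical adjusted over the list alone. Early stress and touch genes had 15 of 30 slower and 1 faster, or 17 and 1 adjusted over the list alone, with the calmodulin-like genes TCH2 and CML38 slower by 0.95 and 0.89 (camera adjusted p = 0.00132, adjusted p = 0.575 with an estimated correlation). Clock genes had 5 of 17 slower and 1 faster (camera adjusted p = 0.00789, adjusted p = 0.478 with an estimated correlation), and type-A response regulators had 3 of 6 slower, ARR4 by 0.61 (camera adjusted p = 0.0202, adjusted p = 0.345 with an estimated correlation). Pathogen response genes had 3 of 7 slower, or 5 adjusted over the list alone (camera adjusted p = 0.0468, adjusted p = 0.478 with an estimated correlation). SAUR genes leaned the other way, with 7 of 14 faster and 3 slower, also adjusted over the list alone (median -0.24; camera adjusted p = 0.00143, adjusted p = 0.432 with an estimated correlation). Xylem markers had 3 of 9 faster, IRX6 by -0.27, or 4 adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.478 with an estimated correlation). The heat shock protein list had no member passing (median -0.09; camera adjusted p = 0.00132, adjusted p = 0.719 with an estimated correlation).

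In vcs sov, slower declines were more widespread against sov. CIL changed by 1.54 (SE 0.10) log2 units per h, from a half-life of 30.4 min in sov to 137.1 min, and BT1 and BT2 by 1.24 (SE 0.12) and 1.22 (SE 0.14), from 26.5 and 24.5 min to 58.2 and 48.8 min. TCP11 changed by 1.18 (SE 0.09), from 33.3 to 96.4 min. The abscisic acid (ABA) receptor genes PYL6 and PYL5 were slower by 1.33 (SE 0.13) and 1.09 (SE 0.09), the cell wall gene EXLA1 by 1.15 and the kinase gene CIPK20 by 1.07. Faster declines were seen for PP2CA and ABI1, protein phosphatases that repress ABA signalling, at -0.96 (SE 0.10) and -0.56 (SE 0.08). They were also seen for MYB59 at -0.82 (SE 0.10) and RAP2.4 at -0.63 (SE 0.09), from 95.4 to 47.8 min. By 30 min RAP2.4 had fallen alike here too, by -0.875 (log2) in sov and -0.848 in vcs sov. At 120 min it stood at -1.314 in sov and -2.478 in vcs sov. The chaperone genes HSP101 and HSP70, with slopes of 0.74 and 0.20 in sov, differed by -0.80 (SE 0.23) and -0.56 (SE 0.14), to slopes of -0.06 and -0.36 in vcs sov. CRF6 differed by -0.72 (SE 0.07). Its log2 change from 0 min rose in sov from -1.67 at 60 min to -0.38 at 120 min, while in vcs sov it went from -1.18 to -1.71. Over 0 to 60 min, CRF6 and PP2CA differed by 0.41 and 0.34 with no call, ABI1 (-0.39), HSP70 (-0.35) and MYB59 (-0.88) were not called either, and HSP101 lost its call over 0 to 480 min (-0.08) and without replicate 1 (-0.84, adjusted p = 0.0612). HSP70 also lost its call without replicate 2 (-0.56, adjusted p = 0.0552). SOV was slower by 0.29 (adjusted p = 0.00830), a call that ended over 0 to 480 min (0.02, adjusted p = 0.498), over 0 to 60 min (0.49, adjusted p = 0.0584) and with each course centred on its median (0.13, adjusted p = 0.186).

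Of 15463 genes, limma called 7108 slower and 418 faster in vcs sov than in sov (94.4% slower). With each course centred on its median, 2930 were slower and 3318 faster (46.9% slower), and without the 2 rRNA reference genes 9013 were slower and 360 faster. The count of 7526 fell to 4810 without replicate 2 of every genotype. The difference was largest among transcripts that decline fastest in WT. With genes split by their WT slope into 5 equal sets, the median difference from the fastest set to the slowest was 0.37, 0.25, 0.17, 0.10 and 0.02 log2 units per h, and 77.8%, 65.8%, 50.5%, 30.8% and 7.1% of genes were called slower.

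Histone genes had 17 of 20 slower in vcs sov and none faster, HTB1 by 0.93 and HTA13 by 0.90 (median 0.46; camera adjusted p = 3.94e-05, adjusted p = 0.459 with an estimated correlation). JAZ genes had 10 of 11 slower, JAZ6 by 0.95 and JAZ8 by 0.92 (median 0.49; camera adjusted p = 0.0103, adjusted p = 0.459 with an estimated correlation). Type-A response regulators had 4 of 6 slower, ARR9 by 0.89, ARR4 by 0.82 and ARR7 by 0.78 (median 0.54; camera adjusted p = 0.0103, adjusted p = 0.238 with an estimated correlation). For these 3 lists the counts were identical adjusted over the list alone. Cell cycle genes had 17 of 27 slower, or 18 adjusted over the list alone, LGO by 0.74 and CYCD3;2 by 0.66 (camera adjusted p = 0.0312, adjusted p = 0.459 with an estimated correlation). Cytoplasmic mRNA decay factors had 19 of 28 slower and 1 faster, LSM1B by 0.59 and RRP4 by 0.54, with no camera call (adjusted p = 0.0934). Plastid-encoded genes had 37 of 114 faster and 10 slower, or 35 and 10 adjusted over the list alone (median -0.10; camera adjusted p = 1.25e-23, adjusted p = 0.238 with an estimated correlation). Heat shock protein genes had 4 of 19 faster (camera adjusted p = 6.19e-09, adjusted p = 0.459 with an estimated correlation) and xylem markers 2 of 9 faster (camera adjusted p = 5.01e-07, adjusted p = 0.238 with an estimated correlation). Mitochondrion-encoded genes had 3 of 60 slower and 1 faster, or 1 and 0 adjusted over the list alone (camera adjusted p = 7.06e-11, adjusted p = 0.459 with an estimated correlation). Nuclear photosystem genes had 4 of 48 slower and 1 faster, or 1 and 0 adjusted over the list alone, with a median of 0.02 that turned to -0.13 relative to the median gene (camera adjusted p = 4.93e-05, adjusted p = 0.459 with an estimated correlation). Phloem markers had 1 of 7 slower (camera adjusted p = 0.0409, adjusted p = 0.459 with an estimated correlation).

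**Figure D4:**
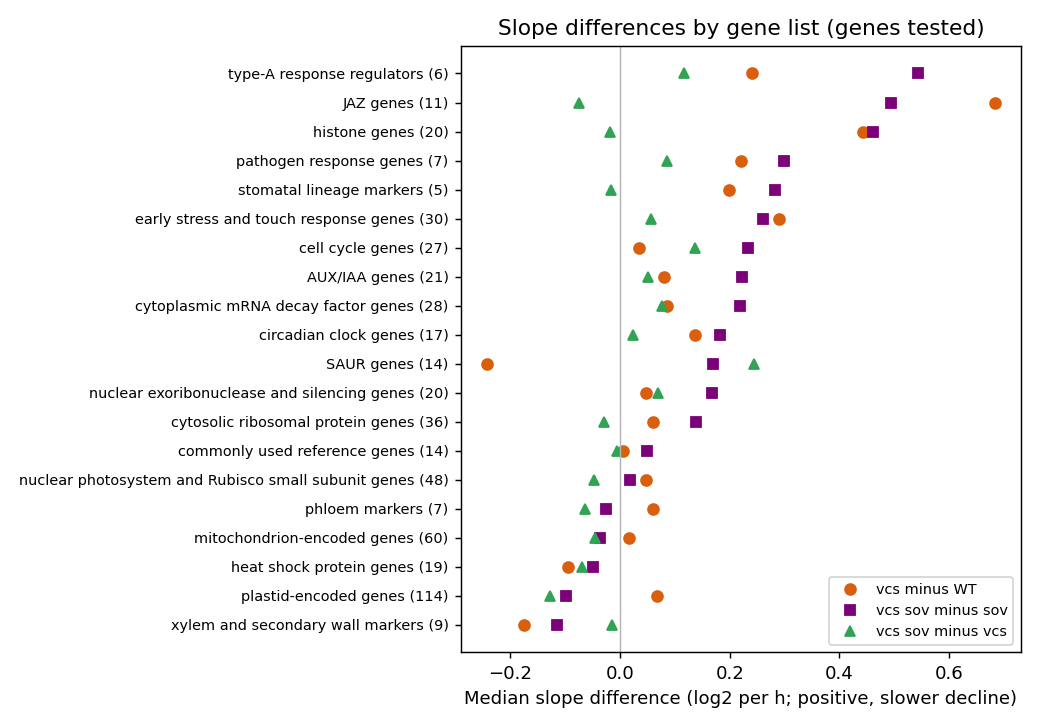
Median slope difference per gene list in log2 units per h (x axis), with 1 line per list of at least 5 tested genes (y axis) and 1 marker for each of 3 comparisons. Among the lists fixed before the data were examined, JAZ genes had the largest median in vcs against WT (0.68). Among the same lists, type-A response regulators had the largest median in vcs sov against sov (0.54).

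Between vcs sov and vcs, BBX15 was slower in vcs sov by 0.94 (SE 0.13) log2 units per h, from a half-life of 27.0 min in vcs to 46.7 min, and PYL6, MAKR6, UBP17 and the phosphate response gene SPX1 were slower by 0.77, 0.77, 0.76 and 0.72. PUB29, a U-box gene, and CDF1 (AT5G62430) were faster by -0.67 and -0.56. Of 15463 genes, limma called 1552 slower and 172 faster; with each course centred on its median, 1007 were slower and 951 faster, and without the 2 rRNA reference genes 2956 were slower and 222 faster. The total of 1724 calls depends on single courses. It was 2765 without vcs sov replicate 4, 906, 874 and 1107 without vcs replicate 2, 3 or 4, and 1041, 679 and 1050 without vcs sov replicate 1, 2 or 3. Leaving out replicate 2 or 3 of every genotype gave 311 and 462. Over 0 to 60 min only 39 genes were called, and BBX15, PYL6, MAKR6, UBP17 and CDF1 were not among them. A fit of genotype by time over 96 libraries ended the call of MAKR6 (0.77, adjusted p = 0.0537). SAUR genes had 5 of 14 slower, or 8 adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.523 with an estimated correlation). Plastid-encoded genes had 33 of 114 faster and 4 slower, or 46 and 6 adjusted over the list alone (camera adjusted p = 1.93e-27, adjusted p = 0.303 with an estimated correlation). Cell cycle genes had 3 of 27 slower, or 4 adjusted over the list alone (camera adjusted p = 0.00631, adjusted p = 0.523 with an estimated correlation). Camera called 10 lists in all; the other 7, with at most 1 member passing in each direction, lay below the median gene. They were the ribosomal protein, heat shock protein, histone, JAZ, mitochondrion-encoded and nuclear photosystem genes and the phloem markers (camera adjusted p from 1.71e-08 to 0.0354, adjusted p = 0.523 to 0.662 with an estimated correlation).

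The interaction of slopes was positive for 812 genes and negative for 35 of 15463, among them BBX15 at 1.02 (SE 0.19), MAKR6 at 1.02 (SE 0.14), PYL6 at 0.88 (SE 0.18), UBP17 at 0.82 (SE 0.13), the ion channel gene DND1 at 0.75 (SE 0.13) and PUB29 at -0.64 (SE 0.10). This count of 847 is not stable. It was 2025 without vcs sov replicate 4, 1669 without sov replicate 1, and 21, 109 and 211 without replicate 2, 3 or 4 of every genotype. It was 435 and 428 without WT replicate 1 or 4, 415 and 407 without sov replicate 2 or 4, and 417, 401 and 536 without vcs replicate 2, 3 or 4. Without vcs sov replicate 1, 2 or 3 it was 465, 370 and 468. Without the 2 rRNA reference genes, 2305 were positive and 66 negative; with courses centred on their medians, 236 were positive and 256 negative (48.0% positive against 95.9%). Over 0 to 60 min 3 genes were called, none of the 6 genes named here among them. PYL6 also lost its call without replicate 2 (0.77, adjusted p = 0.147) or 4 (0.66, adjusted p = 0.0790) of every genotype, and BBX15 without replicate 2 (0.92, adjusted p = 0.0847). The fit of genotype by time ended the calls of MAKR6 (adjusted p = 0.0980) and PYL6 (adjusted p = 0.0861). Camera called 9 lists, none of them with an estimated correlation. Plastid-encoded genes had 8 of 114 negative and 3 positive, or 24 and 5 adjusted over the list alone (camera adjusted p = 7.19e-38, adjusted p = 0.119 with an estimated correlation). Cell cycle genes had 4 of 27 positive, or 7 adjusted over the list alone (camera adjusted p = 0.00388, adjusted p = 0.456 with an estimated correlation). No member passed in the other 7, which lay below the median gene: early stress and touch, heat shock protein, JAZ, mitochondrion-encoded and nuclear photosystem genes and phloem and xylem markers (camera adjusted p from 5.55e-11 to 0.0386, adjusted p = 0.456 to 0.599 with an estimated correlation).

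The slope differences of vcs in both backgrounds had a Pearson r of 0.692 across 15463 genes. Of the slower genes 2324 were shared, where independent lists would share 1162.1, and of the faster ones 187 against 23.2; 86 were called in opposite directions. Slope differences were nearly unrelated to differences in abundance at 0 min. With abundance taken from 2 replicates and slopes from the other 2, the mean Pearson r over the 6 ways to do so was -0.06 (-0.07 to -0.03) for vcs sov against sov and -0.10 (-0.13 to -0.05) for vcs against WT, across 15289 genes. Of 7095 genes slower in vcs sov than in sov, 40.7% were higher and 27.4% lower at 0 min on nuclear RPM. Of 380 faster genes, RAP2.4 and PP2CA among them, 66.8% were higher and 15.5% lower, and of 7814 without a slope call 40.1% were higher and 30.5% lower. These counts use the same 0 min libraries for both measures. An error at 0 min therefore enters both and favours higher abundance beside a steeper decline.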

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

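Tests chosen after the result was seen are those of the plastid share alone, of low depth, of the rRNA genes among the references and of splits after additive effects; those of plastid plus photosystem reads, of a scaling error, of weaker inhibition and of other splits of the samples were chosen before.

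The RPM of the median nuclear gene at 0 min was 0.64 (log2) higher in vcs sov than in sov. A smaller share of plastid reads in the total cannot be the whole of it, because a shift of 0.166 (SE 0.032) remained without organelle genes. Leaving out the photosystem genes too left 0.064 (SE 0.023), so a smaller share of plastid and photosystem reads together may account for most of the shift and stays open. A change of the transcriptome that comes with the genotype stays open as well, and the design cannot tell a rise of other transcripts from a fall of photosynthesis transcripts. Of 35 splits of the libraries on RPM as deposited, only the real one (1) gave as many genes, 15475 against 0 in the highest other. The smallest share that 35 splits allow is 0.0286, so a chance product of the grouping is made unlikely but is not excluded.

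Slower declines outnumbered faster ones 7108 to 418 in vcs sov against sov. Low depth would spare genes of 10 RPM or more, but 47.7% of them were called slower. A scaling error common to all genes cannot be the whole of the differences, whose median ran from 0.371 in the 3058 genes of steepest WT decline to 0.021 in the 3058 of shallowest (-0.66 across genes), but a common shift leaves both that range and the correlation as they are, so the bound set before was wrong and the balance of calls stays open to it. Weaker inhibition of transcription in vcs sov, which would slow all declines in proportion, stays open too, since 1.11% of 993 genes with a WT half-life under 60 min declined faster, between the values set for and against it, as does slower decay in the genotype itself. Of 35 splits, only the real one (1) reached 7526 genes, with 4572 in the highest other, or 9373 and 2 without the rRNA reference genes.

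The median slope of vcs sov replicate 4 was -0.4454 log2 units per h, far from the other 3 courses at -0.3166 to -0.3056. Leaving the 2 rRNA genes out of the reference set moved it to -0.349, against a mean of -0.305 (SD 0.015) in the others, which is consistent with those genes as the source of most of the gap. It was still the lowest of the 4. The rRNA gene AT3G41768 went from 34.59 to 1174 RPM between 0 and 120 min in that course, and from 358.1 to 764.6, 355.6 to 580.4 and 631.9 to 727.1 RPM in the others. No biological explanation was tested.

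Other single libraries or courses stood apart within their group of 4. The nuclear share at 480 min was 74.19% in vcs sov replicate 1 against 64.57% to 65.32% in the others. VCR at 0 min stood at 71.55 RPM in vcs sov replicate 1 against 61.97 to 63.24. In WT replicate 3 the slope of MYB34 was -2.16 against -1.82 to -1.78, and that of HSP70 was -0.0193 against 0.329 to 0.371. These and the median slope above are 5 of 72 groups examined, where chance gives about 1 in 20.

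The effect of vcs differed between the backgrounds with and without the SOV transgene for 8127 genes in abundance on RPM as deposited, and for 847 in slope. On nuclear RPM the abundance count was 7767. In abundance (log2 nuclear RPM) the interaction was 6.68 for LEA7, 5.84 for CER1, 5.29 for RD20, 5.13 for LTP3 and 4.96 for RAB18, and -4.66 for ACD6, -4.43 for IRT1, -4.40 for CYP82C4, -4.27 for FRO2 and -3.65 for MLP34. In slope (log2 units per h) it was 1.02 for BBX15, 1.02 for MAKR6, 0.88 for PYL6, 0.82 for UBP17, 0.75 for DND1, -0.64 for PUB29, -0.53 for PP2CA, -0.49 for CDF1, -0.46 for FBS1 and -0.43 for HSFB2A. Of 100 splits on RPM as deposited, only the real one (1) gave as many abundance interactions (highest other 0). For slopes, 3 of 100 splits gave as many and the highest gave 3561. That is several times the real count and points to a structure of the samples. The splits exchange courses among all 4 genotypes, and the only 2 above the real count put 7 of the 8 courses with vcs-7 on the same side of the contrast, so the effect of vcs itself enters them and their share does not test an interaction. Of 100 splits of what additive effects of vcs and sov left, only the real one (1) reached 847, with 361 in the highest other, and the same held for the 8127 in abundance (highest other 0). Without the rRNA reference genes the values for exchanged courses were 2371 and 5084. None of these 10 slope interactions was called over 0 to 60 min. Those of PP2CA, CDF1, FBS1 and HSFB2A lost their calls there (-0.24, -0.51, -0.82 and -0.53), in the fit of genotype by time (adjusted p = 0.329, 0.164, 0.190 and 0.0639) and without replicate 2 or 4 of every genotype, and also without several single courses, such as WT replicate 1 or 2; PP2CA, CDF1 and FBS1 lost them with a pseudocount of 0.1 as well. All 4 kept their direction.

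Other splits were counted for the remaining comparisons too. In abundance on RPM as deposited, only the real split (1 of 35) gave as many genes for sov against WT (8, highest other 7), vcs against WT (14006, highest other 0) and vcs sov against vcs (11505, highest other 345). In slope, the same held for vcs against WT (3386, highest other 0) and vcs sov against vcs (1724, highest other 1713, or 3178 and 6 without the rRNA reference genes). For sov against WT in slope the real count was 0, with 3 in the highest other split. All 35 splits had to reach a count of 0, so this test decides nothing there.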

How the results depend on the processing

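Settings chosen after the data were seen are nuclear RPM with no stable scaling, course centring, the next 50 reference genes, the window of 7.5 to 120 min and references without rRNA genes. Over all settings, 5304 values of named genes kept their side of the threshold, 179 kept their direction but lost the call and 16 gained one. Another 19 changed direction with a call in the main fit, in the other setting or in both. The 5304 can include values that changed direction without a call in either. The cause of each change below was not tested unless given. Abundance calls of vcs against WT (14006) went to 9125 after median centring and 9136 with edgeR, both of which remove the shift of the median gene; other abundance counts stayed within 1.5 times under every setting that kept all replicates.

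Slope counts were 3386 for vcs against WT, 7526 for vcs sov against sov, 1724 for vcs sov against vcs, 847 for the interaction and 14994 for WT. At 10 RPM or more, fewer genes were tested and they were 1875, 4015, 994, 405 and 7907. Over 0 to 60 min they were 1584, 2661, 39 and 3 for the first 4. Over 0 to 480 min, vcs against WT gave 8994, vcs sov against vcs 6067 and the interaction 3367. For those last 2, no stable scaling gave 4597 and 3529, 200 reference genes 2705 and 1556, and references without rRNA genes 3178 and 2371. Nuclear RPM with no stable scaling gave 2677 for vcs sov against vcs, and course centring 492 for the interaction. For sov against WT the count was 0 under all settings.

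The WT slopes of DL3, RIP1, POM1, CAC1 and FBA2 (-0.08 each) were 0.18 with no stable scaling, 0.25 on nuclear RPM with none and 0.01 with the next 50 reference genes. Over 0 to 60 min the slope differences of CRF5 in vcs against WT (0.25), and of PP2CA (0.34) and CRF6 (0.41) in vcs sov against sov, changed direction, as did the WT slope of AOX1A (-0.04). None of those 4 was called there.

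With an estimated correlation, camera called 0 lists in every nuclear RPM and slope comparison and for WT slopes, except 1 for vcs against WT in nuclear RPM. The correlation of abundance with slope differences for vcs sov against sov was -0.055, and -0.011 with no stable scaling.

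Leaving out replicates (20 fits) gave 5 to 8 abundance calls for sov against WT, the lowest without replicate 3. Slope counts ranged from 1840 (without replicate 3) to 3860 for vcs against WT, from 4810 to 8489 for vcs sov against sov, from 311 to 2765 for vcs sov against vcs and from 21 to 2025 for the interaction. The last 3 were lowest without replicate 2, and all 4 were highest without vcs sov replicate 4. The labels do not say that replicate numbers mark a shared batch, and not every same-numbered pair correlated above 0.1, so the samples were not treated as paired. Deviations did so in 16 of 24 same-numbered pairs for abundance (median 0.152) against 10 of 72 others (-0.058), and in 11 of 24 against 12 of 72 for slope, which hints at a partly shared effect; not every sample correlated best with its own number. With the replicate number as a block, slope interactions rose to 1462, and the other counts stayed within 1.5 times. The authors' normalized values could not be run in place of RPM, since that table holds group means only. Small slope changes are hard to detect where few genes change. In the simulation at this depth and n, with its preset dispersion, 13.4% of changes of 0.25 log2 units per h were recovered. Few genes were changed there, which makes the adjusted threshold stricter than where many differ. In vcs sov against sov, 65.8% of a set of 3058 genes with a median difference of 0.249 were called slower.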

Other observations

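The tests in this part were chosen after the results were seen, and so were the 3 gene lists named first.

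All 8 clade A protein phosphatase 2C genes tested, which repress the response to abscisic acid (ABA), were higher in vcs sov than in sov on nuclear RPM, with a median of 3.23 (log2). HAI1, HAI3 and ABI2 were higher by 5.75 (SE 0.20), 4.04 (SE 0.26) and 3.37 (SE 0.12), n = 4 per genotype. In vcs against WT, 7 of them were higher (median 0.94), and the interaction passed for all 8 (median 1.72). Of 9 ABA receptor genes, 4 were higher and 3 lower in vcs sov than in sov, PYL6 by -2.47 (SE 0.30) and PYL7 by 1.65 (SE 0.12). In slope, 6 of 8 receptor genes declined more slowly in vcs sov than in sov (median 0.77 log2 units per h) and none faster, while 3 of 5 phosphatase genes declined faster (median -0.27) and none slower. PP2CA turned to 0.34 over 0 to 60 min, where ABI1 lost its call (-0.39, adjusted p = 0.0868). PYL6 was less abundant in vcs sov and declined more slowly, by 1.33 (SE 0.13), while PYL5 and PYL1 were more abundant (0.47 and 0.41) and also declined more slowly (1.09 and 0.73).

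Of 11 iron uptake genes, 5 were lower and 5 higher in vcs sov than in sov. The lower ones include IRT1, FRO2 and FRU, the transcription factor that drives both, at -1.31 (SE 0.23). The higher ones include bHLH38 and bHLH39, partners of FRU, at 3.36 (SE 0.89) and 3.05 (SE 0.67). The interaction was negative for 5 genes and positive for none. DCP2, the decapping enzyme that works with VCS, stood at 7.67 RPM in WT, 9.04 in sov, 14.5 in vcs and 244.1 in vcs sov, and differed by 4.18 (log2 nuclear RPM) between vcs sov and sov.

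A first hypothesis was that the higher SOV transcript level in the vcs genotypes comes from the transgene, through copy number or position. The rise of 2.61 (SE 0.15) from sov to vcs sov, which carry no transgene, excludes this as the whole cause. A second was that the SOV transcript decays more slowly in vcs. The slope difference between vcs and WT was -0.07 (SE 0.09), which does not decide it. Against sov, vcs sov had a slower decline of SOV in the main fit, as given above. That call ended over 0 to 60 min (0.49, limma adjusted p = 0.0584) and over 0 to 480 min (0.02, adjusted p = 0.498). The second hypothesis therefore stays open.

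Another hypothesis was that slower decay raises abundance at 0 min in vcs sov against sov. With slopes taken from 7.5 to 120 min, so that no library is used in both, the correlation across genes was -0.097, where a value above 0.3 had been set for it and one below 0.1 against it. Slower decline was thus not accompanied by higher abundance across genes. Whether transcription differs between the genotypes cannot be read from these libraries.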
